A study of Homo sapiens with 6 samples.

How the data were processed

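Messenger RNA was measured by RNA sequencing in ZR-75-30 cells, a human breast adenocarcinoma line, after infection with an empty control lentivirus or with a lentivirus that carries CDK12. Per the labels, each of the 2 groups held 3 biological replicates, polyadenylated RNA was captured, and libraries were made with a strand-marking kit and read from both ends. The labels do not say whether the replicates came from separate infections, so each p-value measures the difference against the spread between these libraries.

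The deposited files hold raw counts of reads per gene symbol, per the file values, which are whole numbers with different totals in each library. Per the submitters' processing notes, the tools were CASAVA 1.8, STAR 2.6.0c and featureCounts from Subread 1.6.2, with the genome build hg19. The strand setting of the counting, the gene annotation and the treatment of reads that map to several places are not given in the sources used here. Antisense and overlapping genes, and genes with near-identical copies, are therefore uncertain. The 6 libraries list the same 26364 symbols, with totals from 21178163 to 26543653 counts. A count of 3, the upper limit that a count of 0 allows, corresponds to 0.113 to 0.142 CPM (counts scaled to a fixed library total) across libraries; this floor covers counting error only.

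Genes were kept with the default filter of edgeR 4.0.16 (filterByExpr, minimum count 10, minimum total count 15), which left 14665 genes. Library sizes were scaled by TMM, and the groups were compared with edgeR's quasi-likelihood F test with group as the only term. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries. The transduced gene was also compared with an exact permutation test, for which 3 against 3 libraries cannot give a p under 0.1.

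Before the data were examined, 37 gene lists with 970 symbols were fixed from textbook knowledge of pathways, complexes and cell types, and 957 of the symbols are in the files. Older symbols were matched through the RefSeq synonyms of GRCh38.p14. Lists with at least 5 tested genes, 36 in all, were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists. The remaining list, of mitochondrially encoded genes, has no symbol in the files and was not analysed here. List members were counted as higher or lower at the threshold over all genes tested, and again adjusted over the list alone; where no second count is printed, both adjustments gave the same counts. The ErbB, PI3K and WNT lists follow themes for which the study is known, and are not independent evidence of a direction in these samples.

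The rule for naming genes was fixed before the data were examined. It took 14 genes always, CDK12 and its cyclin among them, and the 12 largest rises and 12 largest falls. Those had to pass the threshold, reach a mean of 5 CPM in the higher group and show no overlap between the groups' libraries, and symbols for uncharacterised loci were left out. From each list it took up to 4 members with the smallest p in the direction of most called members and up to 2 in the other; the text prints a part of these. Genes named outside the rule are said to be so.

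The alternatives were other scalings (the size factors of DESeq2 1.42.0, upper-quartile factors, total counts only), no filter beyond 1 count, a stricter filter of 1 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, the replicate number as a block, and leaving out each library in turn. The counts of genes were also taken with a test against a fold of 1.2 (glmTreat) and with CDK12 left out of the counts. The lists were also tested with an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction and compares them with no other genes. The test was run on simulated counts for this comparison, with 200 changed genes among the 14530 that passed the filter. It recovered 46% of genes changed 1.2-fold, 78% at 1.5-fold, 94% at 2-fold and 98% at 4-fold, and 6.51% of its calls were false. As many genes were raised as lowered, and far fewer were changed than the 5143 called in the data. These rates need not hold for the real comparison, and the simulation does not test the scaling. On simulated counts camera called the 1 list lowered 1.2-fold and 0 of the others, and 0 of 36 lists when none was changed; genes were simulated as independent. Gene types, gene spans and sequences for the closing section came from GENCODE 29 on GRCh38, and no coordinates are given.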

Results

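The data cover 6 RNA-seq libraries of ZR-75-30 breast cancer cells, 3 infected with the empty control virus and 3 with the CDK12 virus. ZR-75-30 is an established line with amplified ERBB2. CDK12 is a kinase that pairs with cyclin K and phosphorylates RNA polymerase II during elongation. The series title gives the purpose as the search for targets of CDK12, and the comparison asks which transcripts differ when CDK12 is overexpressed. The control libraries held 23106302, 21178163 and 25014857 counts, and the CDK12 libraries 26543653, 23954798 and 23628890. The 10 genes with the most counts took 6.03% to 6.38% of each library.

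CDK12 transcripts were 27.3-fold higher in the cells given the CDK12 virus. The level rose from 77.9 ± 4.61 CPM to 2124 ± 116 CPM (SD, n = 3 per group), a log2 fold change of 4.77 (SE 0.05; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.1e-31). Each library matched its label, with 72.8 to 81.8 CPM in the controls and 2009 to 2240 CPM in the CDK12 libraries. CCNK, the gene of the partner cyclin, was at 76.6 ± 2.62 CPM in controls and 72.2 ± 0.92 CPM with the CDK12 virus (log2 fold change -0.09, SE 0.05, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.153). CDK13, the closest relative of CDK12, was at 119 ± 4.22 and 110 ± 1.52 CPM (log2 fold change -0.10, adjusted p = 0.0664 by the same test). The exact two-sided permutation test on the 6 CDK12 values gave p = 0.1, the smallest that 3 against 3 libraries allow. The counts do not part viral from endogenous CDK12 transcripts.

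**Figure D1:**
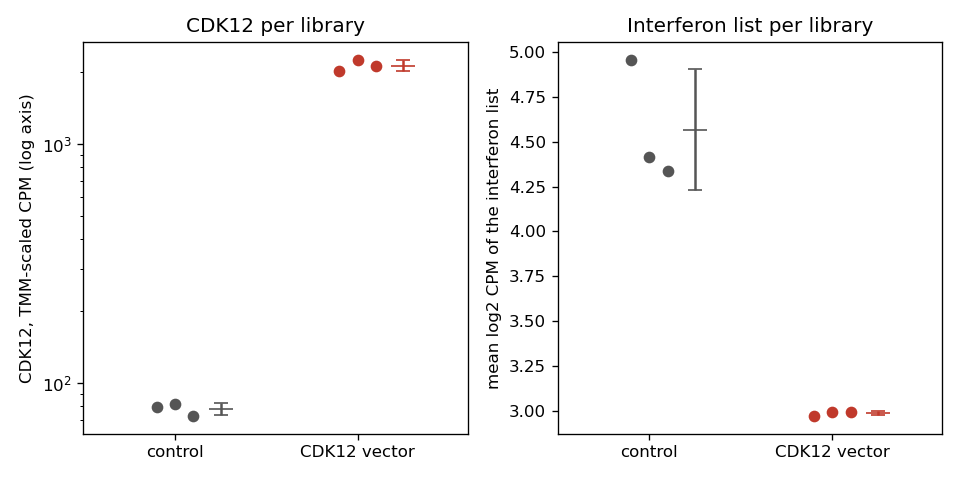
CDK12 in TMM-scaled CPM on a log axis (left) and the mean log2 CPM of the 41 genes of the interferon list (right), with a point for each library and the mean ± SD of 3 libraries per group. CDK12 lies at 72.8 to 81.8 CPM in controls and 2009 to 2240 CPM in CDK12 libraries, and the interferon mean at 4.34 to 4.95 in controls and 2.98 to 3.00 in CDK12 libraries.

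The largest falls in the CDK12 libraries were taken among called genes that reached a mean of 5 CPM in the higher group without overlap. They were those of 8 interferon-stimulated genes and of CSMD3, HMCN1, CHL1 and TENM3. Some genes of lower abundance fell as far, such as C9 (log2 fold change -5.55) and PCDH15 (-5.37), with CDK12 levels under the floor of counting. IFI44L, an interferon-stimulated gene, went from 10.8 ± 5.22 to 0.248 ± 0.12 CPM (log2 fold change -5.38, SE 0.36). OAS2, IFIT1, IFI6, IFI44, OAS1, MX1 and OAS3, all interferon-stimulated, were also among the 12 largest falls under these limits. Their log2 fold changes ran from -3.98 for OAS2 to -2.70 for OAS3. Of the other 4, CSMD3 fell from 18.4 ± 0.89 to 1.02 ± 0.16 CPM (log2 fold change -4.16, SE 0.12). Under the same limits the rises were smaller. After CDK12 itself, LTA, the gene of lymphotoxin alpha, went from 1.71 ± 0.45 to 5.07 ± 0.31 CPM (log2 fold change 1.59, SE 0.16). ABCC12, CDNF, LDLRAD1, NKPD1 and F7 rose with log2 fold changes between 1.05 for F7 and 1.34 for ABCC12. STRC (1.18), SRP14-AS1 (1.17), ADCY10P1 (1.09) and CYP21A2 (1.05) also rose on the log2 scale. STRC and CYP21A2 have near-identical pseudogenes, ADCY10P1 is a pseudogene and SRP14-AS1 an antisense gene, so their counts are uncertain.

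By edgeR's quasi-likelihood test, 5143 of 14665 genes (35.1%) passed a Benjamini-Hochberg adjusted p of 0.05, 2371 higher and 2772 lower in the CDK12 libraries. That share is the background for the counts of list members below. Most shifts were small: the median fold was 1.24 among higher and 1.19 among lower genes, and 163 higher and 225 lower genes reached 2-fold. Among all genes tested, 6693 (45.6%) showed no overlap between the groups' libraries, where chance gives 10%. Higher genes made up 46.1% of the calls with TMM, 59.6% with upper-quartile factors (3164 higher, 2144 lower) and 61.7% with total counts (3324 higher, 2064 lower), so the balance of directions depends on the scaling. Against a fold of 1.2, 459 higher and 479 lower genes passed.

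**Figure D2:**
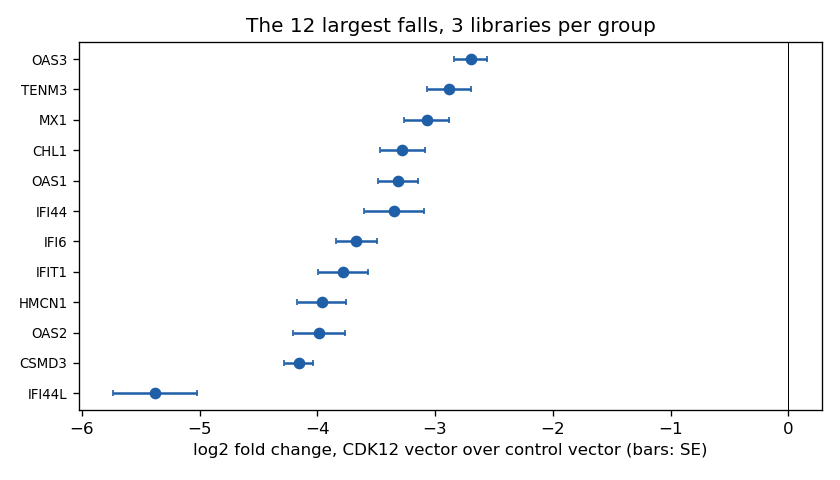
Log2 fold changes, CDK12 over control libraries, of the 12 largest falls among called genes that reached 5 CPM in the higher group without overlap. Bars are SE, n = 3 libraries per group. They run from IFI44L at -5.38 to OAS3 at -2.70.

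Interferon-stimulated genes fell as a group. Of 41 members tested, 36 fell and the other 5, HERC5, IFITM2, EPSTI1, MX2 and TRIM22, did not pass the test; adjusted over the list alone, 37 were lower. The median log2 fold change was -1.23, a 2.35-fold lower level. IRF9, a subunit of the interferon-activated transcription factor ISGF3, fell from 74.3 ± 11.3 to 22.8 ± 1.04 CPM (log2 fold change -1.71, SE 0.08). OAS1 fell from 32.9 ± 11.6 to 3.30 ± 0.11 CPM and OAS3, which like OAS1 encodes a sensor of double-stranded RNA, from 91.6 ± 31.5 to 14.2 ± 1.24 CPM. The list had a camera adjusted p of 1.06e-68, and an adjusted p of 0.0981 with an estimated correlation. The controls were not alike: the mean log2 CPM of the list was 4.95 in control replicate 1 against 4.41 and 4.34 in the other controls, and without that library the median log2 fold change was -0.999 with 36 members lower.

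Inflammatory and antigen presentation genes went apart. Of 22 NF-kappaB and inflammatory targets, 17 fell and 4 rose. The chemokine gene CCL2 fell from 37.4 ± 2.57 to 18.6 ± 0.32 CPM, LTB from 19.4 ± 0.89 to 8.34 ± 0.71 CPM and TNF from 6.91 ± 0.84 to 3.24 ± 0.20 CPM, while CXCL2 (log2 fold change 0.33) and SOD2 (0.19) rose. LTA, which neighbours TNF and LTB in the genome, was among the largest rises. Of 19 antigen presentation genes, 8 rose and 3 fell. The class II genes CD74 (50.3 ± 2.49 to 81.7 ± 2.45 CPM), HLA-DRA (19.9 ± 1.11 to 29.7 ± 2.35 CPM) and HLA-DRB1 (7.51 ± 0.39 to 12.1 ± 0.57 CPM, a gene with near copies) rose, as did B2M (671 ± 22.3 to 813 ± 29.2 CPM). TAP1 and TAP2, the peptide transporters of the class I route, fell with log2 fold changes of -0.43 and -0.40. The camera adjusted p was 7.62e-08 for the NF-kappaB list and 0.0192 for antigen presentation; with an estimated correlation the adjusted p was 0.06 and 0.721. Without control replicate 2 the antigen presentation list had a camera adjusted p of 0.144, and with fry its adjusted p was 0.0506.

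Genes of DNA replication and mitosis were modestly lower. Of 36 G1/S and replication genes, 21 fell and 15 did not pass (22 lower when adjusted over the list alone), with a median log2 fold change of -0.21. MCM4, a subunit of the replicative helicase, fell from 374 ± 6.76 to 290 ± 6.41 CPM and CDC45, its cofactor, from 10.3 ± 0.75 to 6.66 ± 0.15 CPM. Of 36 G2/M genes, 24 fell and 12 did not pass (26 lower when adjusted over the list alone), with a median log2 fold change of -0.24. CCNB1, the gene of cyclin B1, fell from 56.1 ± 2.58 to 44.1 ± 3.32 CPM and KIF23, a kinesin of cytokinesis, from 41.4 ± 1.24 to 31.0 ± 1.08 CPM. Of 16 replication-dependent histone genes, 5 fell and 1, HIST1H1D, rose (DESeq2 Wald adjusted p = 0.0567); HIST2H2BE fell with a log2 fold change of -0.41. The camera adjusted p was 6.61e-06 for G1/S, 3.25e-06 for G2/M and 0.535 for histones. With an estimated correlation the adjusted p was 0.0981 for G1/S and 0.316 for G2/M. With the size factors of DESeq2, 3 histone genes were lower, and with upper-quartile factors or total counts 1 was lower and 1 higher. Polyadenylated RNA holds few histone transcripts, and their genes are near copies of each other.

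Cholesterol synthesis genes fell almost throughout. Of 23 genes of the pathway and its SREBP2 targets, 19 fell and 1, TM7SF2, rose, with a median log2 fold change of -0.28. SQLE, squalene epoxidase, fell from 280 ± 11.9 to 201 ± 6.15 CPM. FDPS and MSMO1, enzymes of the same pathway, fell with log2 fold changes of -0.36 and -0.40. Of 16 fatty acid synthesis genes, 3 fell, SCD, FASN and ACLY, and 1 rose, THRSP. SCD, a desaturase, fell from 552 ± 21.4 to 423 ± 35.1 CPM. The camera adjusted p was 8.83e-10 for the cholesterol list, with an adjusted p of 0.06 with an estimated correlation, and 0.501 for fatty acid synthesis. With upper-quartile factors or total counts, 3 fatty acid genes were higher and 3 lower. For fatty acid synthesis the median (-0.04) and the mean (0.04) differed in sign.

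Targets of TGF-beta and of YAP/TEAD, immediate early genes and basal markers were also lower. Of 20 TGF-beta targets, 11 fell and 1, SKIL, rose (2 higher when adjusted over the list alone), and TGFB2, which encodes a ligand of the pathway, went from 54.0 ± 0.88 to 25.4 ± 1.95 CPM. Of 16 YAP/TEAD targets, 10 fell and 1, AXL, rose; CYR61, in both lists, fell from 104 ± 2.71 to 66.0 ± 3.44 CPM. Of 29 immediate early and AP-1 genes, 14 fell and 1, ATF3, rose (15 lower when adjusted over the list alone). JUN, an AP-1 subunit, fell from 104 ± 4.64 to 70.1 ± 3.43 CPM, and SPRY4 and DUSP5, feedback inhibitors of growth factor signalling, fell with log2 fold changes of -0.50 and -0.41. Of 18 basal and myoepithelial markers, 13 were tested. KRT5, KRT14, KRT6A, KRT6B and CNN1, named here outside the rule, did not pass the filter, so nothing is said of them. Of the 13, 9 fell and 1, ACTA2, rose (10 lower and 2 higher when adjusted over the list alone). TP63, a basal transcription factor, fell from 2.27 ± 0.14 to 0.280 ± 0.04 CPM. The camera adjusted p was 3.25e-06 for TGF-beta, 1.37e-05 for YAP/TEAD, 4e-06 for immediate early genes and 1.42e-05 for basal markers. With an estimated correlation the adjusted p was 0.0647, 0.0761, 0.308 and 0.0732 in the same order. ATF3 did not pass without control replicate 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.088) or without CDK12 replicate 1 (0.0603), and SKIL did not without control replicate 3 (0.0687) or CDK12 replicate 2 (0.0943).

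The 4 receptor genes of the ErbB family fell. ERBB2, the amplified receptor gene of this line, fell from 8656 ± 275 to 7357 ± 257 CPM (log2 fold change -0.23, SE 0.04; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.05e-05). EGFR fell from 9.24 ± 0.44 to 6.88 ± 0.37 CPM and ERBB3 from 485 ± 8.95 to 441 ± 10.6 CPM. ERBB4 went from 2.03 ± 0.45 to 0.479 ± 0.06 CPM. Of 28 genes of the ErbB list, 5 fell and 4 rose, EGF and SOS2 among the latter. Of 31 genes of IRS, PI3K and AKT signalling, 8 fell and 2, IRS1 and IRS2, rose. IRS1, an adaptor of insulin receptors, was at 0.508 ± 0.16 CPM in controls and 0.945 ± 0.04 CPM with CDK12 (log2 fold change 0.88, SE 0.29; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0199). INPP4B, a lipid phosphatase, fell from 97.0 ± 3.76 to 70.1 ± 1.91 CPM. Neither list passed camera (adjusted p = 0.788 for ErbB and 0.2 for PI3K), and both follow themes for which the study is known, so that they are not independent evidence. With upper-quartile factors the ErbB list had 6 higher and 5 lower members, and with total counts 6 and 4, so the order of its counts turned. The ErbB median (0.00) was above 0, while its mean (-0.08) and camera direction were below. IRS1 did not pass with the DESeq2 Wald test (adjusted p = 0.104) or without control replicate 2 (0.104), control replicate 3 (0.0513) or CDK12 replicate 2 (0.055), and ERBB3 did not with total counts (0.0518).

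Among WNT pathway genes, the inhibitor gene DKK1 fell and the ligand gene WNT3 rose. Of 30 ligands, receptors and pathway members, 8 fell and 1, WNT3, rose. DKK1, a secreted WNT inhibitor, fell from 85.3 ± 2.87 to 37.2 ± 3.00 CPM, and the ligand gene WNT7B from 55.9 ± 0.58 to 43.1 ± 0.94 CPM. WNT3 rose from 1.32 ± 0.02 to 2.15 ± 0.28 CPM (log2 fold change 0.71, SE 0.19; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00457). WNT1 had 2, 5 and 2 counts in the control libraries and 15, 6 and 7 in the CDK12 libraries, and was not tested. Of 15 WNT/beta-catenin target genes, 5 fell and 3 rose: MYC fell from 115 ± 4.71 to 89.6 ± 2.10 CPM and CCND1, the gene of cyclin D1, from 856 ± 12.5 to 688 ± 8.24 CPM, while the stem cell receptor gene LGR5 rose from 0.860 ± 0.22 to 1.86 ± 0.48 CPM and ASCL2 from 8.50 ± 0.99 to 11.5 ± 1.39 CPM. By camera, the adjusted p was 0.18 for the pathway and 0.818 for the targets, and both lists follow themes for which the study is known and are not independent evidence. With upper-quartile factors or total counts the pathway list had 7 higher and 4 lower members, so the balance of its calls turned with the scaling, while its median stayed below 0 (-0.08 with TMM, -0.04 with both others). The targets then had 4 higher and 3 lower members. The targets had a positive median (0.08) and mean (0.10) but a negative camera direction.

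DNA repair genes, for which CDK12 is a known regulator, went both ways. Of 29 homologous recombination and Fanconi anemia genes, 4 rose, 6 fell and 19 did not pass. Among all genes tested 35.1% passed, so calls at about this rate do not set the list apart. BRCA1 fell from 13.8 ± 0.68 to 11.7 ± 0.40 CPM (log2 fold change -0.24, SE 0.08; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0175), and EXO1, FANCI and FANCD2 fell with log2 fold changes of -0.40, -0.32 and -0.33. RAD51C (0.39) and RAD50 (0.22) rose on the same scale. Of 20 checkpoint kinases and partners, 4 rose and 6 fell (7 lower when adjusted over the list alone). CHEK1, a replication checkpoint kinase, fell from 12.6 ± 1.36 to 9.41 ± 0.65 CPM, ATM rose from 28.2 ± 1.87 to 34.3 ± 1.58 CPM, and ATR was at 68.2 ± 1.62 and 70.9 ± 3.92 CPM without passing the test. The camera test had an adjusted p of 0.779 for homologous recombination and 0.788 for checkpoint genes. BRCA1 did not pass with the DESeq2 Wald test (adjusted p = 0.0651) or without control replicate 1 (0.0926) or CDK12 replicate 2 (0.0658). With upper-quartile factors or total counts the checkpoint list had 4 higher and 4 lower members.

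Luminal identity genes went in no common direction. Of 28 estrogen response and luminal genes, 4 rose and 7 fell. The estrogen receptor gene ESR1 was at 51.2 ± 2.50 CPM in controls and 46.8 ± 1.02 CPM with CDK12 (log2 fold change -0.13, SE 0.05; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0594). The luminal keratin genes KRT8 and KRT18 fell with log2 fold changes of -0.20 and -0.17, and XBP1, a transcription factor of secretory cells, rose from 1848 ± 45.9 to 2299 ± 93.2 CPM. Of 18 genes of the ERBB2 amplicon on chromosome 17, 5 rose and 6 fell (6 of each when adjusted over the list alone). PPP1R1B rose from 30.0 ± 1.40 to 47.6 ± 1.52 CPM and PGAP3, which neighbours ERBB2, fell from 733 ± 29.7 to 629 ± 12.8 CPM. Of 11 breast stem cell associated genes, 4 fell, ITGA6 and NOTCH1 among them, and 1, LGR5, rose. Camera gave an adjusted p of 0.782 for luminal genes, 0.818 for the amplicon and 0.486 for stem cell genes, whose median (-0.07) and mean (0.02) differed in sign. The luminal list had 6 higher and 4 lower members with upper-quartile factors or total counts, the amplicon list 6 and 5 or 7 and 5, and ESR1 passed without control replicate 3 (adjusted p = 0.0382).

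Oxidative phosphorylation and heat shock genes were lower, while hypoxia and glycolysis genes went both ways. Of 48 nuclear-encoded oxidative phosphorylation genes, 23 fell and 25 did not pass, with a median log2 fold change of -0.12. COX6B1, a subunit of cytochrome c oxidase, fell from 145 ± 4.58 to 113 ± 5.52 CPM. Of 16 heat shock chaperones, 10 fell and 1, HSPA4L, rose (2 higher when adjusted over the list alone). HSPB1 fell from 518 ± 23.5 to 398 ± 20.2 CPM and HSP90AB1 from 2542 ± 29.7 to 2226 ± 46.9 CPM. Of 29 hypoxia and glycolysis genes, 10 fell and 7 rose (13 lower when adjusted over the list alone), with GAPDH falling from 5134 ± 119 to 4286 ± 116 CPM and PFKM rising from 76.0 ± 1.45 to 92.9 ± 3.83 CPM. Of 19 NRF2 targets, 3 fell, TXNRD1 and TALDO1 among them, and 16 did not pass. Camera gave an adjusted p of 0.000804 for oxidative phosphorylation, 0.0339 for heat shock, 0.455 for hypoxia and 0.788 for NRF2. With an estimated correlation the adjusted p was 0.774 for oxidative phosphorylation and 0.562 for heat shock, and with fry it was 0.0804 for oxidative phosphorylation. With total counts, oxidative phosphorylation had 15 lower and 2 higher members, hypoxia and glycolysis 7 of each and NRF2 targets 2 of each; with upper-quartile factors these were 17 lower and 2 higher, 8 lower and 7 higher, and 2 of each. The heat shock list did not pass camera with upper-quartile factors (adjusted p = 0.0886) or total counts (0.096), nor without control replicate 2 (0.0741), control replicate 3 (0.0698) or CDK12 replicate 3 (0.0864), and TALDO1 did not pass with upper-quartile factors (0.0871), total counts (0.104) or without control replicate 3 (0.0876) or CDK12 replicate 2 (0.161).

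Apart from CDK12 itself, most genes of transcription and RNA processing did not pass, and those that passed went both ways. In the list of CDK12 and other elongation kinases, 3 of 17 rose, CDK12, MNAT1 and CCNT1, and 2 fell, HEXIM1 among them. Of 22 genes for 3' end processing, 4 rose and 1, CPSF1, fell. PCF11, a termination factor, rose from 80.0 ± 3.68 to 94.1 ± 1.64 CPM and CSTF3 from 51.1 ± 1.77 to 64.7 ± 3.58 CPM. Of 42 splicing factors, 8 rose and 8 fell, with CLK1, a kinase of splicing factors, at 0.24 and SRSF4 at -0.17 on the log2 scale. Of 65 cytosolic ribosomal protein genes, 11 rose and 8 fell (9 higher when adjusted over the list alone). RPS3A rose with a log2 fold change of 0.22 and RPL28 fell with -0.27; these genes have many pseudogenes. Camera gave an adjusted p of 7.62e-08 for the CDK12 list but 0.9 when CDK12 itself was left out, a test chosen after the data were seen, 0.38 with limma-voom and 0.0981 with an estimated correlation. With upper-quartile factors and total counts, splicing factors had 11 and 12 higher against 4 and 3 lower members, and ribosomal protein genes 14 and 15 higher against 4 and 3 lower. The 3' end list then had 7 higher and 1 lower, and the CDK12 list 4 and 5 higher with HEXIM1 no longer past. The adjusted p by camera was 0.354 for 3' end processing, 0.9 for splicing and 0.972 for ribosomal proteins. For splicing the median (-0.01) lay below 0 and the mean and camera direction above, and for ribosomal proteins the median and mean (-0.01 each) lay below 0 and the camera direction above. MNAT1 did not pass without CDK12 replicate 1 (adjusted p = 0.119). HEXIM1 did not pass with upper-quartile factors (adjusted p = 0.0746), total counts (0.09) or without control replicate 3 (0.0718) or CDK12 replicate 3 (0.0507), and CCNT1 did not with the DESeq2 Wald test (0.0583) or without control replicate 3 (0.263) or CDK12 replicates 1 (0.0527) or 2 (0.0905).

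Stress and cell death genes were mixed. Of 29 ATF4 and amino acid stress genes, 7 rose and 3 fell. DDIT3, a stress-induced transcription factor, rose from 43.5 ± 1.75 to 60.0 ± 3.42 CPM and ATF5 fell from 54.5 ± 1.93 to 39.9 ± 1.34 CPM. Of 22 unfolded protein response genes, 3 fell and 1, XBP1, rose; the chaperone gene CALR fell with a log2 fold change of -0.19. Of 25 p53 targets, 3 rose and 4 fell, and RRM2B, a ribonucleotide reductase subunit, rose from 184 ± 6.83 to 254 ± 8.56 CPM. Of 26 apoptosis regulators, 5 rose and 5 fell (6 lower when adjusted over the list alone). CASP9 rose from 10.4 ± 0.44 to 15.6 ± 1.77 CPM, and BCL2L1, which encodes an inhibitor of apoptosis, fell from 129 ± 4.83 to 103 ± 4.81 CPM. Of 15 NOTCH genes, 4 rose and 4 fell, with DLL1 at 0.38 and JAG1, another ligand gene, at -0.39 on the log2 scale. Camera gave an adjusted p of 0.56 for ATF4, 0.818 for the unfolded protein response, 0.818 for p53, 0.972 for apoptosis and 0.788 for NOTCH. With upper-quartile factors or total counts, p53 targets had 6 higher and 3 lower members and the unfolded protein response 4 and 3, against the other order with TMM. For p53 and apoptosis the median was below 0 and the mean and camera direction above, and for NOTCH the median (-0.04) and camera direction were below 0 and the mean (0.06) above.

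Markers of other cell types went both ways. Of 9 mesenchymal and fibroblast markers that could be tested, 3 rose, COL1A1, S100A4 and SNAI1, and 3 fell (4 when adjusted over the list alone), FN1 from 87.7 ± 2.84 to 65.3 ± 1.75 CPM. Of 7 leukocyte markers, 2 rose, CSF1R and CD14, and 2 fell, PTPRC from 2.96 ± 0.11 to 0.359 ± 0.06 CPM and ITGAM from 37.4 ± 1.76 to 27.9 ± 1.82 CPM. The mesenchymal list had a camera adjusted p of 0.972 and leukocytes one of 0.425; for leukocytes the median (0.26) was above 0 and the mean (-0.15) and camera direction were below. CSF1R and CD14 did not pass with the DESeq2 Wald test (adjusted p = 0.149 and 0.147). Without control replicate 1, control replicate 3 or CDK12 replicate 3 neither passed (adjusted p = 0.0553 to 0.182), CSF1R did not without CDK12 replicate 2 (0.0748), and CD14 did not without CDK12 replicate 1 (0.0602). PTPRC, ERBB4 and TP63 belong to 100 genes of low abundance chosen for a fall of at least 4-fold, 59 of them with a span of at least 200 kb.

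**Figure D3:**
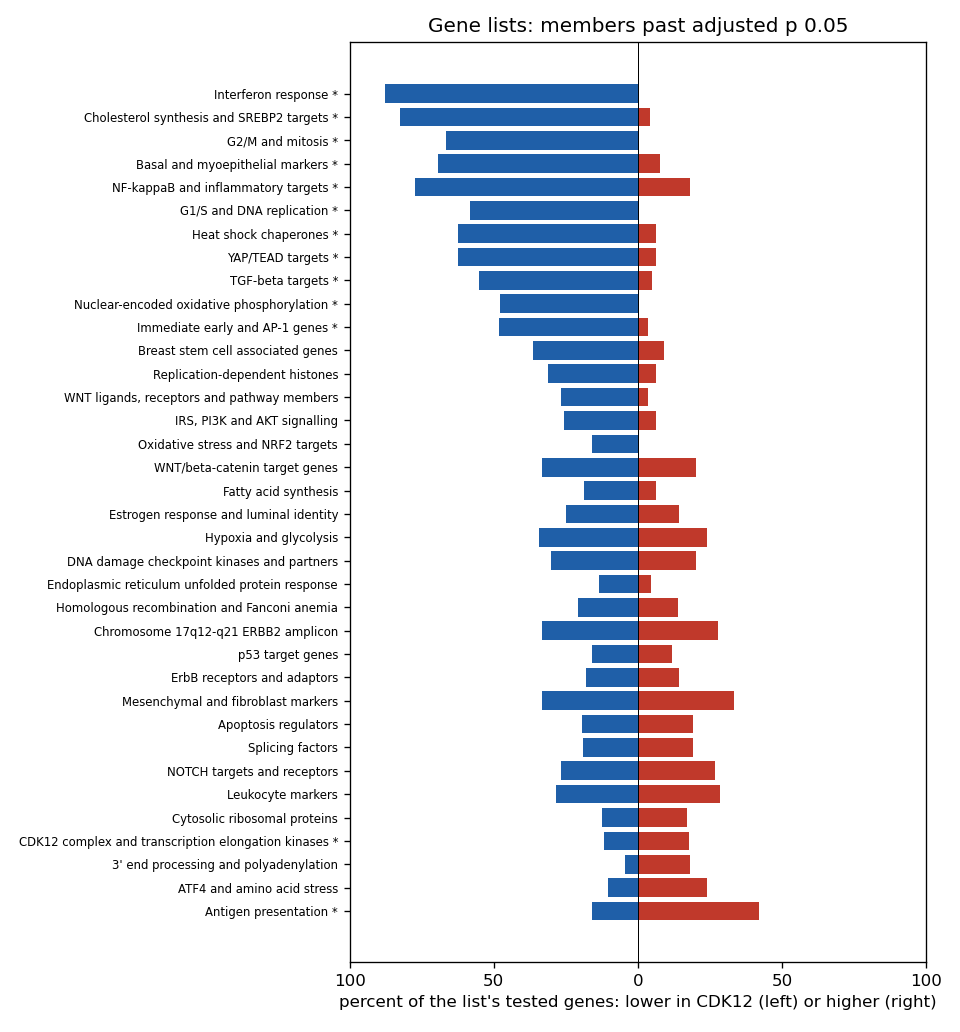
Percent of each list's tested genes that were lower (left, blue) or higher (right, red) in the CDK12 libraries at a Benjamini-Hochberg adjusted p of 0.05; an asterisk marks the 13 lists that passed camera with the preset correlation. The interferon list had 87.8% of its genes lower.

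Of the 36 lists, 13 passed camera with the preset correlation, 11 lower and 2 higher, and with an estimated correlation 0 passed. In that test 8 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.06, while fry called 18. Fry sets a list against no other genes, and 7 lists passed with it that did not pass camera: PI3K (adjusted p = 0.022), WNT pathway members (0.0149), breast stem cell (0.00915), hypoxia and glycolysis (0.0225), NRF2 targets (0.0315), 3' end processing (0.0148) and histones (0.022). For 10 lists the median, mean and camera direction differed in sign.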

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

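The alternatives were chosen before the data were examined, except the CDK12 list tested without CDK12, which was added afterwards and left 12 lists past the threshold. The log2 fold change of CDK12 lay between 4.73 and 4.81 over its 14 alternatives and passed the threshold in each. The count of higher genes lay between 1699 (DESeq2 Wald test) and 3324 (total counts) and that of lower genes between 2064 (total counts) and 2951 (no filter), and without 1 library between 1789 and 2310 higher and 2199 and 2735 lower. Against a fold of 1.2 the counts were 459 higher and 479 lower, since that test asks for a larger change: 2485 of the 5143 calls were below 1.2-fold. With the replicate block, 2330 genes were higher and 2776 lower, and 13 lists passed. The replicate numbers do not pair the libraries, whose deviations from their group means correlated at -0.07, 0.06 and 0.03 between same-numbered libraries, and 2 of the 6 libraries correlated best with their own number. The block ended the calls of 2 named genes and of 0 lists.

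The count of lists lay between 11 and 13 over the other alternatives, with 0 for the estimated correlation and 18 for fry. The estimated correlation between genes reached 0.811 in the interferon list, against the preset 0.01. It was below the preset in the cholesterol (0.00055), NF-kappaB (0.00127), TGF-beta (-0.00065) and basal (-0.0496) lists, which lost their calls too. For these 4 lists the values argue against a higher correlation as the cause. The cause of the lost calls was otherwise not tested. Apart from the CDK12 list, the estimated correlation gave the highest adjusted p of each of the lists that had passed. Among 205 named genes besides CDK12, 2737 of 2862 comparisons with an alternative kept direction and side of the threshold, 124 kept the direction and lost the call, 1 gained it, and 0 turned. Among lists, 488 of 540 comparisons kept both, 23 lost and 7 gained a call, and 22 turned direction, in lists that did not pass in either setting; the cause was not tested. The adjusted p of these was 0.776 (stricter filter) and 0.811 to 0.998 (without 1 library) for mesenchymal markers. For apoptosis regulators it was 0.996 (limma-voom), 0.999 (replicate block), 0.641 (fry) and 0.788 to 0.998 (without 1 library). For ribosomal proteins it was 0.944 (no filter), 0.996 (limma-voom), 0.933 (replicate block), 0.901 (fry) and 0.0813 to 0.946 (without 1 library). It was 0.962 for the unfolded protein response (total counts), 0.893 (fry) and 0.746 to 0.949 (without 1 library, turned without CDK12 replicate 2) for splicing factors, and 0.746 to 0.94 for NOTCH (without 1 library, turned without control replicate 1). The ranges without 1 library cover all 6 libraries, those that did not turn the direction included. Depth limits genes near 0.113 to 0.142 CPM, the level that 3 counts give.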

Other observations

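The tests of technical explanations for the interferon genes and for the 100 low-abundance genes were chosen after the result was seen. So were those of abundance and chromosome for the zinc finger genes. The test of GC content and the splits of the libraries were set before.

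Zinc finger genes leaned higher. Of 413 tested genes whose symbol is ZNF and a number, a family of mostly repressive transcription factors, 145 were higher and 30 lower in the CDK12 libraries by edgeR's quasi-likelihood test, and with other scalings 147 to 188 were higher and 23 to 30 lower. ZNF555 rose from 20.9 ± 1.15 to 34.4 ± 0.66 CPM and ZNF84 from 58.2 ± 1.47 to 85.3 ± 3.91 CPM, while ZNF689 fell from 58.4 ± 1.52 to 38.6 ± 1.76 CPM (n = 3 per group); these 3 were chosen after their values were seen. On chromosome 19, which holds large clusters of the family, 91 of 201 were higher and 9 lower, and elsewhere 54 of 212 were higher and 21 lower. Long non-coding RNA genes, by GENCODE's gene types, had 125 of 632 higher and 20 lower, against 2101 of 13260 protein-coding genes higher and 2732 lower. Within strata of abundance, their odds of being higher were 1.202 times those of protein-coding genes (95% interval 0.975 to 1.48) and their odds of being lower 0.218 times (0.139 to 0.341). Genes are not independent replicates, so these intervals are too narrow.

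Many of the low-abundance genes with the deepest falls had a long span. Outside the interferon list, 100 genes were at least 4-fold lower by the fitted fold change and under 1 CPM in the CDK12 libraries, and HMCN1, CHL1, TENM3, TP63, PTPRC and ERBB4 are among them. Their median level was 1.35 CPM in controls and 0.151 CPM with CDK12, where 9 of them had at most 3 counts over the 3 libraries together. In GENCODE 29, 59 of the 100 span at least 200 kb. Protein-coding members of the set were so long more often than other protein-coding genes of like control level (9.77%). The odds ratio was 13.6 (95% interval 8.76 to 21.3, Fisher's exact test over 2812 genes). As genes are not independent replicates, this interval is too narrow. The 100 were chosen for their fall, and most long genes of that control level are not among them: of 324 such protein-coding genes, 59 are in the set, 131 were lower and 19 higher by edgeR's quasi-likelihood test, with a median log2 fold change of -0.37. Of the 2488 shorter ones, 212 were lower and 504 higher, with a median of 0.13; this count was made after the result was seen.

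Type III interferon transcripts were scarce: IFNL1, IFNL2 and IFNL3 had 72 counts over the 3 control libraries and 16 over the 3 CDK12 libraries, and IFNB1 7 and 4.

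By edgeR's quasi-likelihood test, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split, 1 of the 10, gave 2371 higher and 2772 lower genes, and the other splits gave 0 each, with at most 291 genes in 1 direction at an unadjusted p under 0.05; other tools were not run on them. For lists the real split gave 13 and the others between 4 and 9, the highest being 9, each with camera at the preset correlation. Each of those splits still sets 2 libraries of a virus against 1, so it keeps a part of any real difference between the groups. Each also mixes both viruses on a side, so that difference adds to the spread and few genes could pass. Their counts of 0 therefore do not measure chance.

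The fall of interferon genes held under each scaling, with the list's median log2 fold change nearest to 0 at -1.19. The scalings differed little: the median over all genes was 0.003 with TMM and 0.046 with total counts. The choice among them therefore does not account for the fall, but a scaling unlike these was not tried. Leukocytes or fibroblasts in the control libraries would bring their abundant transcripts, but the median control level of 40 markers was 0.192 CPM, against 32.9 CPM for the interferon genes. Of genes abundant in such cells, VIM was at 0.293, SPARC at 0.0735, LAPTM5 at 0.508 and CORO1A at 0.465 CPM; FN1 (87.7), S100A4 (85.7), COL1A1 (48.2) and ITGAM (37.4 CPM) were higher, and COL1A1 and S100A4 rose with CDK12 while FN1 and ITGAM fell. What stays open is a difference between transduced cell pools: the group means differ by 6.62 times the SD within groups, as they would also if CDK12 were the cause, and the design cannot part these. An effect of CDK12 stays open too.

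For the 100 low-abundance genes, genomic DNA in the control libraries would raise silent loci. Yet 3702 non-coding genes under 0.3 CPM summed to 108 ± 2.66 CPM in controls and 113 ± 1.41 CPM with CDK12, a log2 ratio of 0.0577. These non-coding genes were chosen by their mean over all 6 libraries, so loci raised strongly in the controls would have been left out. A lower yield of all long genes is argued against by 730 genes of at least 200 kb and 5 CPM. Their median log2 fold change was -0.047 (quartiles -0.16 and 0.06). They were chosen by their mean over both groups, so long genes near 5 CPM in controls that fell deeply were left out. HMCN1, CHL1 and TENM3 are such genes. The values therefore cover abundant long genes and not those of low abundance. Leukocytes or fibroblasts in the control libraries stay open: of 40 markers of these cells, 12.5% were 4-fold lower with CDK12. These were PTPRC and COL3A1 (0.602 to 0.109 CPM), both among the 100 genes, COL1A2 (0.296 to 0.0511), POSTN (0.185 to 0.0387) and SPARC (0.0735 to 0.0124). With CDK12 the means of all but PTPRC lay under 0.113 to 0.142 CPM, and that of SPARC did so in controls too. That floor holds for 1 library, and a mean over 3 libraries can resolve lower levels. COL3A1 had 14, 13 and 14 counts in the control libraries and 1, 3 and 4 in the CDK12 libraries. VIM was not lower, at 0.293 CPM in controls and 0.397 CPM with CDK12. Other forms of this test were tried and set aside: 2.5% with a floor of 1 CPM in controls, which few markers can reach, and a median control level of 0.379 CPM for VIM, SPARC, LAPTM5 and CORO1A, which were picked with their levels known. An effect of CDK12 and a difference between transduced pools stay open and were not tested. The labels do not say how many infections were made with each virus, so the design cannot part these.

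For the zinc finger genes, low abundance was argued against by an odds ratio of 2.67 for being higher (95% interval 2.16 to 3.29) over 10 strata of abundance. A gain of chromosome 19 was argued against by the other 763 protein-coding genes of that chromosome, whose median log2 fold change was -0.0654 (quartiles -0.18 and 0.12). The trend on GC content and transcript length moved genes by an SD of 0.04. After its removal, the 410 zinc finger genes with a sequence still lay 0.15 above other protein-coding genes (95% bootstrap interval 0.13 to 0.17 from 2000 draws). As genes are not independent replicates, this interval and that of the odds ratio are too narrow. Reads shared between members of the family stay open, as the treatment of such reads is not given. An effect of CDK12 and a difference between the transduced pools stay open as well and were not tested.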
